A study of Pyrus pyrifolia with 12 samples.

How the data were processed

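RNA sequencing counts of fruit skin from 4 pear varieties were analysed, with 3 libraries per variety. Per the labels' protocols, total RNA was extracted with a CTAB method from skin of untreated mature fruit in 3 biological replicates, and libraries were made with an NEB Next Ultra kit. The fruit came from orchards in Yizheng, Jiangsu. The authors deposited 1 table for the whole series, which pairs each of 43732 gene identifiers with a position, a length, Swiss-Prot and Pfam hits, a raw read count per library and an FPKM value per library. The count columns are whole numbers that were not normalised, per the file headers and the values. The FPKM values were computed by the authors from the gene length and a library total, per the file headers, and the total they imply was between 0.9198 and 1.1055 times the sum of the counts of the library, 1 constant per library over all genes with more than 50 reads. FPKM values were not tested, because the counts were there. The aligner, the counting tool, its strand setting, the genome build and the annotation are not given in the sources used here. Coordinates are printed only for genes on the 17 numbered chromosomes. Of the genes, 30296 (69.3%) had a Swiss-Prot name, and 8198 had no read in any library. No pair of libraries held identical counts, and 0 columns of values were left without a sample.

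Each library was placed in its variety by its label. Variety is tied to harvest day except between SuCui NO.1 and CuiYu, which were both taken at 105 days after full bloom, so a difference between other varieties can reflect the variety, the day or both. Samples of the Chili variety named in the protocols were not analysed here. The design, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined.

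Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the variety as the group, which left 26307 genes tested and 17425 not tested. Library sizes were scaled by TMM, CPM values use these scaled sizes, and 1 mean per variety was fitted with glmQLFit to all 12 libraries, which share 1 estimate of the spread (common biological coefficient of variation 0.41). The 7 contrasts were Akibae against the equally weighted mean of the other 3 varieties, taken on the log scale, and the 6 pairs of varieties. They were tested with glmQLFTest, and p values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as the fold change divided by the square root of its F statistic. Where a variety had 0 reads over its 3 libraries, a fold is given as a lower bound against a floor of 3 reads over those libraries, and with 1 to 3 reads as a ratio with an exact 95% counting interval. Depth was 11981445 to 15136559 counts per library, so that the floor of 3 reads was 0.0728 to 0.0772 CPM. A gene was called higher, or lower, in Akibae than in each other variety when all 3 pairwise tests passed in that direction, and the chance overlap was estimated from 20 simulations of 4 unchanged groups.

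The 20 gene lists were written from the known biology of fruit skin, russet and neighbouring cell types, and held 2511 genes, none in more than 1 list. They were matched to the recommended name of the Swiss-Prot hit, after the columns had been read and before any value was looked at, and 13 names that matched a pattern without belonging to the list were removed. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over all 140 list tests, with camera with an estimated correlation and fry beside it. A list with fewer than 5 tested members would have had no list test. Of the 140 list tests, 21 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.29 and the unadjusted p was under 0.05 in 8. In 22 of the 140 tests the median, the mean and the direction of the test did not share a sign.

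Named genes had to carry a Swiss-Prot name and a mean of at least 1 CPM over the 12 libraries. In Akibae against the mean of the others, they were the 4 highest and the 4 lowest folds among genes that passed all 3 pairwise tests of Akibae with the same sign, and in each list the member past the threshold with the largest fold in each direction. In each pair of varieties, they were the 3 largest folds past the threshold in each direction without overlap of the libraries, of which at most the first 2 per direction are given, and in each list that passed, the member with the largest fold in the direction of the list. Several named genes share their Swiss-Prot name with other genes in the table, and reads split between near-identical copies make the level of a single copy uncertain.

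The tests were tested on simulated data for the 26307 genes, with counts drawn from the means, dispersions and library sizes of the real libraries and 100 genes changed by a log2 of 1 and 100 by a log2 of 2 in the simulated Akibae libraries. For Akibae against the mean of the others, edgeR recovered 10 of 100 genes changed by a log2 of 1 and 49 of 100 changed by 2, and DESeq2 recovered 30 and 73. For Akibae against Nijisseiki, edgeR recovered 2 and 41 of 100, and DESeq2 19 and 61. Of the edgeR calls, 3 of 63 and 2 of 46 fell on unchanged genes. A list of 25 genes lowered by 1 gave a camera p of 1.8e-28 and a list of 25 unchanged genes one of 0.41. The simulated genes were drawn independently of each other, so these lists do not test the preset correlation of 0.01. In the real libraries the correlation estimated for Akibae against the mean of the others was 0.15 for wax, 0.39 for suberin and 0.49 for photosynthesis. In this simulation, differences of about 1 on the log2 scale were mostly missed in the 2 comparisons. Few genes were changed in it, so the adjusted threshold asked for a smaller unadjusted p than in the real fit. In the real libraries 2596 and 665 genes passed in these comparisons, 2132 and 630 of them with an absolute log2 fold change of at least 1. The simulated shares may therefore understate what the real tests recover.

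The alternatives were DESeq2's median-ratio factors and upper-quartile factors in place of TMM, no filter except 1 read in total, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, an added minimum log2 fold change of 1, only the libraries of the 2 varieties compared, the replicate number as a block, camera with an estimated correlation, and each of the 12 libraries left out in turn. Of the 6 pairs of varieties, only Nijisseiki and SuCui NO.1 had a correlation of deviations from the variety means over 0.1 for each of the 3 pairs of libraries with the same number (0.2 to 0.37). For them a fit of the 6 libraries with the replicate number as a block was added, the pairing coming from the values and not from the labels. Results were compared with 60 random regroupings of the libraries, the real one included, and, for pairs, with all 10 splits of the 6 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and NumPy 2.4.6.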

Results

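The study concerned russet skin, the brown corky surface that some pears form in place of a smooth waxy one. Fruit skin of the Asian pear Pyrus pyrifolia was sequenced from 4 varieties, Akibae, Nijisseiki, SuCui NO.1 and CuiYu, with 3 libraries per variety and 12 libraries in total. Fruits were taken at maturity, which the labels place at 120 days after full bloom for Akibae, 135 for Nijisseiki and 105 for both SuCui NO.1 and CuiYu. Variety and harvest day were therefore tied together except between SuCui NO.1 and CuiYu. A further variety named in the protocols, Chili, was not analysed here. The sources used here do not give the skin type of any variety, and Akibae was taken as the brown-skinned variety from general knowledge before the data were examined.

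The total count per library was 12877896, 11981445 and 13256963 in Akibae replicates 1, 2 and 3, and 12063305, 13071172 and 13551896 in those of Nijisseiki. In SuCui NO.1 the totals were 13492741, 13422358 and 13192163, and in CuiYu 15136559, 13489198 and 13660440. Of the 43732 genes in the table, 26307 had enough reads to be tested. Levels are given below as CPM, which scales counts to a common library total, mean ± SD over the 3 libraries of a variety. Intervals and floors given below cover counting error only. A count of 0 reads does not tell an unexpressed gene from one that is absent in a variety, or whose sequence differs too much from the reference to be counted, so folds against 0 reads are folds of counted reads. Coordinates are those of the deposited table, whose genome build is not given in the sources used here, and gene names are its Swiss-Prot best hits, so a name gives the nearest known protein.

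On the first 2 principal components of log2 CPM, which held 31.8% and 26.1% of the variance, SuCui NO.1 and CuiYu lay apart from each other and from the other varieties, while Akibae and Nijisseiki replicates 2 and 3 lay close together. Akibae and Nijisseiki parted on the third component, at 37.3 to 59.5 against -123.2 to -44.4. Akibae libraries lay from -107.9 to -85.3 on the first component, CuiYu libraries from 63.1 to 69.2 and SuCui NO.1 libraries from 84.6 to 129.8. Nijisseiki replicates 2 and 3 lay at -89.1 and -87.2, whereas the library labelled Nijisseiki replicate 1 lay at -25.6. That library also differed from replicates 2 and 3 in the on or off state of 137 and 118 genes, where on meant at least 10 CPM and off at most 0.5 CPM. The other pairs of libraries of the same variety differed in 6 to 44 genes.

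**Figure D1:**
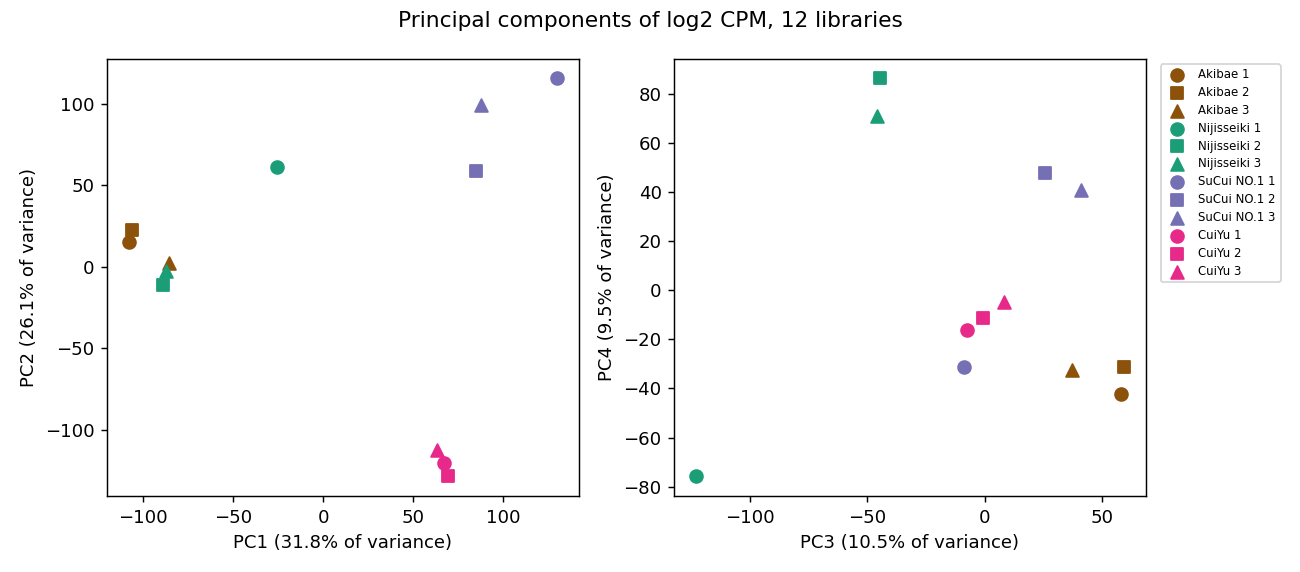
Principal components 1 against 2 (left) and 3 against 4 (right) of log2 CPM, with the percent of variance on each axis; 1 point per library, colour for the variety and shape for the replicate number. The library labelled Nijisseiki replicate 1 (green circle) lies at -25.6 on component 1, apart from replicates 2 and 3 at -89.1 and -87.2.

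The first comparison set Akibae against the mean of the other 3 varieties and asked which genes set the skin of a brown-skinned variety apart. The mean was taken over log2 levels, so few or no reads in another variety can make a call. Genes called here, such as gene28008, need not differ between Akibae and each other variety, which held for 65 genes higher and 215 lower. Unless another comparison is named, adjusted p values of single genes up to the pairwise comparisons are for this contrast. Many genes for the waxy cuticle, the lipid layer that seals the fruit surface, were lower in Akibae. The camera calls of their lists, given below, were lost with an estimated correlation. Of 28 tested members of the cuticular wax list, 15 were lower, 0 were higher and 13 did not pass the test, with a median log2 fold change of -1.76. Adjusted over the list alone, 18 wax members were lower and 1 was higher. Of 23 tested members of the cutin list, 9 were lower, 0 were higher and 14 did not pass, with a median of -1.29. Adjusted over the list alone, 12 cutin members were lower and 0 were higher. Neither median moved when members with no read in a variety were set to the floor of 3 reads over the 3 libraries. The 15 wax members that were lower carried the names of 5 copies of ECERIFERUM 1, which is needed to form the alkanes of the wax, of 2 copies each of 3-ketoacyl-CoA synthase 6, 3-ketoacyl-CoA synthase 10 and an ECERIFERUM 26-like protein, all 3 of which take part in lengthening fatty acids, and of 4 single genes. The latter were an enoyl-CoA reductase, an alcohol-forming fatty acyl-CoA reductase, the wax ester synthase WSD1 and a lipid transfer protein.

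Among the cutin members, gene23333 had the largest fitted difference. It is named cytochrome P450 86A22, of a family that hydroxylates fatty acids into cutin monomers, and lies on chromosome 6 from 9002661 to 9005054. It had 1 read over the 3 Akibae libraries (0.0266 ± 0.0461 CPM), against 28.03 ± 20.7 CPM in Nijisseiki, 48.05 ± 17.8 in SuCui NO.1 and 280.3 ± 24.0 in CuiYu (n = 3 each, adjusted p = 4.5e-05). The ratio to Akibae was 1029 in Nijisseiki (95% counting interval 184.3 to 40690, and 649 without the library labelled Nijisseiki replicate 1), 1864 in SuCui NO.1 (334.1 to 73650) and 10870 in CuiYu (1950 to 429300). The wax member gene21123 (chromosome 16, 2981921 to 2985960) is named non-specific lipid transfer protein GPI-anchored 1, which carries wax lipids to the surface. It had 0 reads in Akibae (adjusted p = 0.00079 against the mean of the others). In CuiYu it stood at 15.1 ± 3.73 CPM, at least 196-fold more. It was at least 22.95-fold higher in Nijisseiki (12.47-fold without the library labelled Nijisseiki replicate 1) and at least 33.05-fold higher in SuCui NO.1. The other cutin members that were lower carried the names HOTHEAD, BODYGUARD 3, BAHD acyltransferase DCR, ABC transporter G family member 32, long chain acyl-CoA synthetases 1 and 2, and 2 glycerol-3-phosphate acyltransferases.

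The camera test of limma, which compares a list with all other genes, gave an adjusted p of 1.7e-11 for the wax list and 9e-09 for the cutin list with a preset correlation. The calls were lost at an adjusted p = 0.29 for wax and 0.30 for cutin with an estimated correlation, where the unadjusted p was 0.0055 and 0.011. The fry test, which asks whether the members of a list move on balance in one direction, gave an adjusted p of 0.0036 for wax and 0.0069 for cutin. Leaving out any 1 of the 12 libraries kept both lists past the threshold with the preset correlation.

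**Figure D2:**
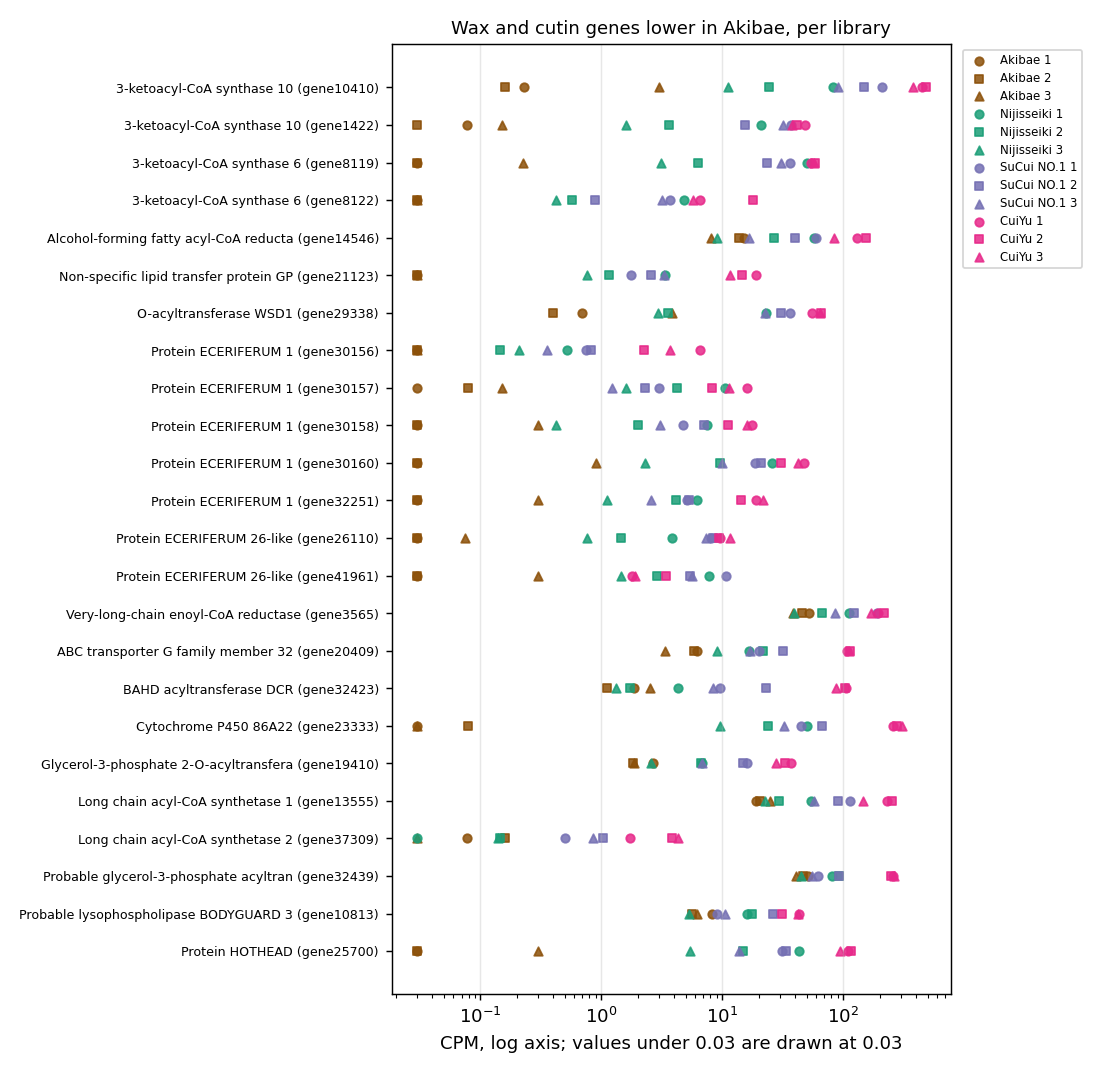
CPM on a log axis of the 24 wax and cutin genes that were lower in Akibae, 1 row per gene and 1 point per library, colour for the variety and shape for the replicate number; values under 0.03 CPM are drawn at 0.03. Most Akibae points (brown) lie at the left of their row, and those of cytochrome P450 86A22 come from 1 read in total.

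Genes of suberin, the corky polymer of wound and russet skin, went both ways. Of 25 tested members, 1 was higher in Akibae, 1 was lower and 23 did not pass, and adjusted over the list alone 1 was higher and 2 were lower. The member that was lower, gene40020 (3-ketoacyl-CoA synthase 20, an enzyme that lengthens fatty acids, chromosome 16, 10103191 to 10106221), fell by 2.10 ± 0.39 on the log2 scale (SE, adjusted p = 0.0067). Its level was 36.4 ± 4.16 CPM in Akibae, 95.9 ± 51.65 in Nijisseiki, 134 ± 65.7 in SuCui NO.1 and 293 ± 35.8 in CuiYu (n = 3 each). The member that was higher, gene3755, is named omega-hydroxypalmitate O-feruloyl transferase, which adds the ferulate of suberin, and was picked out after its values were seen. It stood at 2.95 ± 2.001 CPM in Akibae, 0.735 ± 0.0427 in Nijisseiki, 0.0965 ± 0.109 in SuCui NO.1 and 0.0753 ± 0.130 in CuiYu (n = 3 each, adjusted p = 0.00439, chromosome 1, 6637810 to 6639402). The list as a whole had a median log2 fold change of 0.86 and did not pass camera (adjusted p = 0.18).

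Suberin genes varied widely inside the varieties. Over the 23 members with a mean of at least 1 CPM, the median level was 12.6, 10.5 and 11.3 CPM in Akibae replicates 1, 2 and 3, but 3.39, 21.6 and 8.05 CPM in those of Nijisseiki. It was 2.68, 15.9 and 2.15 CPM in SuCui NO.1 and 5.57, 1.96 and 2.14 CPM in CuiYu. The suberin list passed as higher in Akibae without SuCui NO.1 replicate 2 (adjusted p = 0.0034), without Nijisseiki replicate 2 (0.034) or without CuiYu replicate 1 (0.04). In each case, and in the pairs of varieties below, the library left out had the highest suberin median of its variety. Leaving it out lowers that variety by itself. These passes used the preset correlation. For this list the estimated correlation was 0.39, and with all libraries the adjusted p was 0.99 with an estimated correlation. Passes with a library left out or another setting are given here and below for the preset correlation, and were not run with an estimated one.

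**Figure D3:**
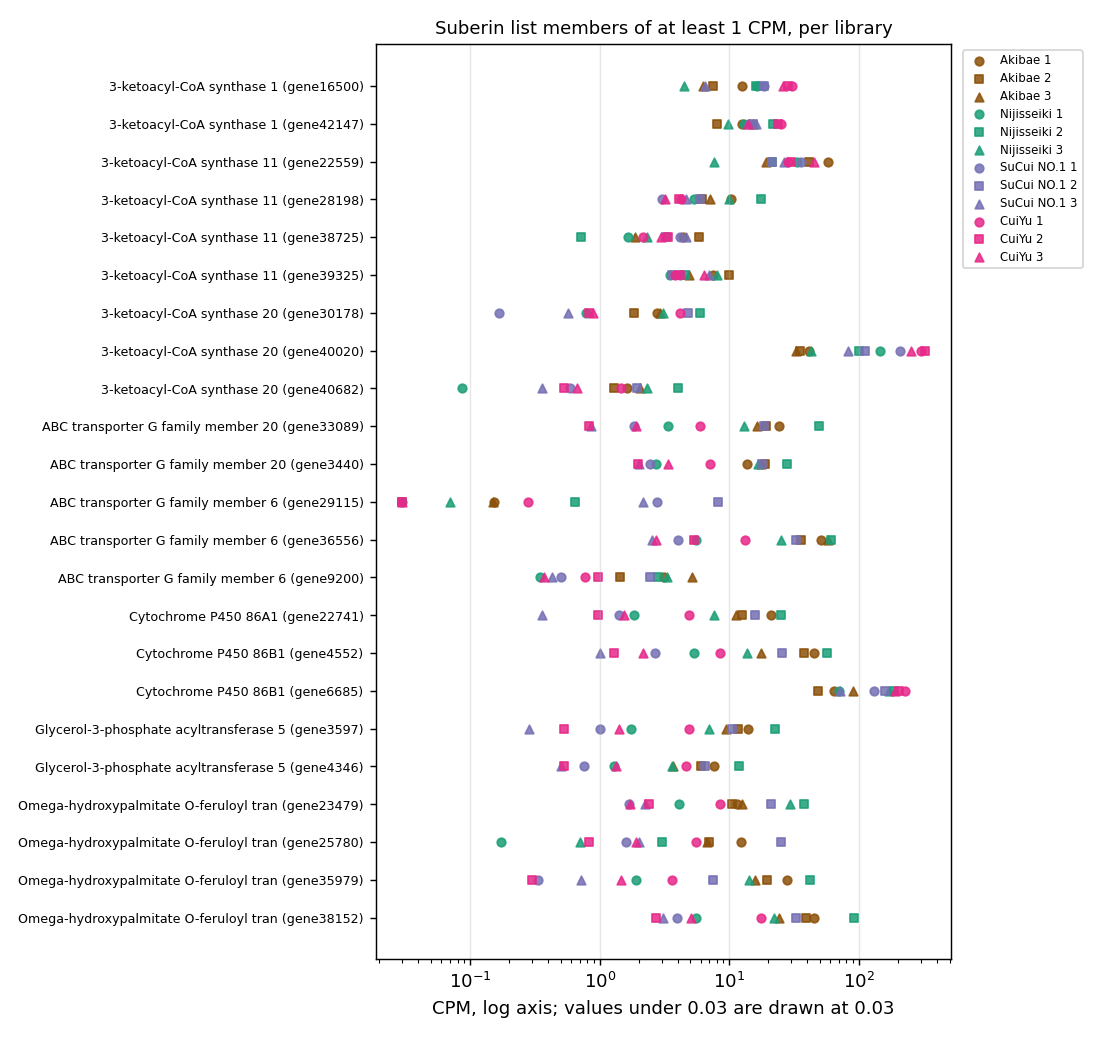
CPM on a log axis of the 23 suberin list members with a mean of at least 1 CPM, 1 row per gene and 1 point per library, colour for the variety and shape for the replicate number; values under 0.03 CPM are drawn at 0.03. For many members the squares of Nijisseiki replicate 2 (green) and SuCui NO.1 replicate 2 (violet) lie to the right of the other points of their variety.

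In the lists around lignin, single genes stood out while the lists did not pass. Of 42 tested lignin polymerisation genes, 3 were higher in Akibae and 1 was lower (also 3 and 1 adjusted over the list alone), at a camera adjusted p of 0.056. Gene7199, a putative laccase-9, of the copper enzymes that oxidise lignin monomers, was higher by 3.41 ± 0.47 on the log2 scale (SE, adjusted p = 0.0012). It stood at 19.6 ± 0.191 CPM in Akibae against 3.26 ± 1.42 in Nijisseiki, 1.77 ± 1.81 in SuCui NO.1 and 1.06 ± 0.485 in CuiYu (n = 3 each, chromosome 2, 17761057 to 17769678). This list passed as higher in Akibae without Akibae replicate 1 (adjusted p = 0.043) or 3 (0.045), Nijisseiki replicate 2 (0.013), SuCui NO.1 replicate 2 (0.0042) or 3 (0.013), or CuiYu replicate 1 (0.031) or 3 (0.045). It also passed when only genes with a mean of at least 1 CPM were tested (0.017). Of 13 phenylpropanoid entry genes, the steps from phenylalanine to coumaroyl-CoA, 1 was higher and 0 were lower (also 1 and 0 adjusted over the list alone, camera adjusted p = 0.52). This was gene28008 (4-coumarate--CoA ligase 2), at 3.54 ± 0.631 CPM in Akibae, 5.30 ± 2.40 in Nijisseiki, 2.16 ± 1.81 in CuiYu and 0 reads in SuCui NO.1 (adjusted p = 0.016, and 0.059 without Akibae replicate 1). Of 56 monolignol synthesis genes, 6 were higher and 4 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.97), where the median was 0.00, the mean -0.01 and the direction of the test up. Gene31267 (cytochrome P450 84A1, a family that makes sinapyl units) had 0 reads in SuCui NO.1 and CuiYu against 2.15 ± 1.69 CPM in Akibae and 5.03 ± 2.56 in Nijisseiki (adjusted p = 0.015, and 0.052 without Akibae replicate 2). Gene39887 (caffeoylshikimate esterase) had 3 reads in Akibae, and its ratio to Akibae was 6.54 in Nijisseiki (95% counting interval 1.94 to 34.3), 41.1 in SuCui NO.1 (13.75 to 202) and 28.3 in CuiYu (9.37 to 139.6). Its adjusted p of 0.021 became 0.096, 0.059 and 0.071 without Akibae replicates 1, 2 and 3.

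Flavonoid and triterpene genes also went both ways. Of 37 tested flavonoid genes, 1 was higher in Akibae and 3 were lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.53). Dihydroflavonol 4-reductase (gene7584), a step toward tannins and anthocyanins, was higher by 1.48 ± 0.22 on the log2 scale (SE, adjusted p = 0.0021), at 126 ± 9.49 CPM in Akibae against 79.6 ± 22.4 in Nijisseiki, 45.98 ± 19.2 in SuCui NO.1 and 25.3 ± 5.18 in CuiYu, and it was not called in Akibae against Nijisseiki alone (adjusted p = 0.338). A gene named flavonol synthase/flavanone 3-hydroxylase (gene33758) fell by 6.03 ± 1.10 (adjusted p = 0.0063), and stood at 0.103 ± 0.0895 CPM in Akibae and 19.6 ± 2.98 in CuiYu. Of 42 triterpene genes, whose products are part of fruit wax, 3 were higher and 3 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.77). A beta-amyrin synthase (gene38942) was higher than the mean of the others (adjusted p = 0.0027). It stood at 11.75 ± 4.98 CPM in Akibae and at 3.75 ± 2.94 in Nijisseiki and a mean of 3.51 in CuiYu. Its ratio to the 2 reads of SuCui NO.1 was 230 (95% counting interval 63.3 to 1905). Squalene monooxygenase (gene26241) fell by 2.40 ± 0.59 (adjusted p = 0.027, and 0.084, 0.083 and 0.083 without Akibae replicates 1, 2 and 3).

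Photosynthesis genes were lower in Akibae as a list. Of 73 tested members, 10 were lower and 2 were higher (11 and 2 adjusted over the list alone), with a median log2 fold change of -1.04 and a camera adjusted p of 8.6e-06. The call was lost at an adjusted p = 0.99 with an estimated correlation, fry did not pass (adjusted p = 0.29), and 25 of 60 random regroupings of the libraries gave a camera p as small. Photosystem I subunit psaK (gene12920) fell by 3.94 ± 1.10 (adjusted p = 0.047), and stood at 0.1 ± 0.173 CPM in Akibae, all from replicate 3, and 3.72 ± 2.35 in SuCui NO.1. Without Akibae replicate 3 no Akibae read was left, and the fitted fall was 7.50 (adjusted p = 0.033). This call ended without any 1 of Akibae replicates 1 and 2, Nijisseiki replicates 2 and 3, SuCui NO.1 replicates 2 and 3 and the CuiYu replicates, at an adjusted p of 0.063 to 0.18, and without the filter on low counts at 0.052. A photosystem II 5 kDa protein (gene41995) was higher than the mean of the others (adjusted p = 0.011). It stood at 7.57 ± 3.40 CPM in Akibae against 0.645 ± 0.422 in CuiYu and 2 reads in SuCui NO.1, the latter a ratio of 149.9 (95% counting interval 41.1 to 1244). Its level in Nijisseiki was 7.91 ± 7.96 CPM.

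The lists for growth, hormones, regulators and other cell types did not pass camera with all 12 libraries. Of 122 cell wall loosening genes 4 were higher in Akibae and 3 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.18), of 34 ethylene genes 1 and 0 (also 1 and 0 adjusted over the list alone, 0.63), and of 27 abscisic acid genes 0 and 0 (also 0 and 0 adjusted over the list alone, 0.67). Endoglucanase 1 (gene11341), a wall-digesting enzyme, stood at 21.05 ± 17.4 CPM in Akibae against 0.909 ± 0.607 in Nijisseiki, a log2 fold change of 5.15 ± 0.55 over the mean of the others (SE, adjusted p = 0.00022, and 4.30 without Akibae replicate 2). The ethylene signalling kinase CTR1 (gene6333) was higher by 0.90 ± 0.13 (adjusted p = 0.0012). Of 74 MYB factors 6 were higher and 9 lower (8 and 9 adjusted over the list alone, camera adjusted p = 0.96), where the median was 0.19, the mean -0.15 and the direction of the test down, and of 64 NAC factors 3 and 2 (2 and 2 adjusted over the list alone, 0.63). MYB1R1 (gene13235) had 0 reads in Akibae (adjusted p = 0.00018 against the mean of the others). It had at least 46.6-fold more in SuCui NO.1, where it stood at 3.597 ± 1.53 CPM. MYB86 (gene28822) stood at 4.87 ± 2.68 CPM in Akibae and 6.46 ± 4.21 in Nijisseiki against 0.146 ± 0.127 in SuCui NO.1 and 1 read in CuiYu (adjusted p = 0.0029). NAC78 (gene37559) fell by 3.19 ± 0.36 (adjusted p = 0.00032). NAC91 (gene12127), at 70.35 ± 50.85 CPM in Akibae, was higher by 1.68 ± 0.48 (adjusted p = 0.049, and by 1.0 without Akibae replicate 1), a call that ended, at an adjusted p of 0.052 to 0.37, without any 1 library except Akibae replicate 3, SuCui NO.1 replicate 3 and CuiYu replicate 3, and at 0.051 when only genes with a mean of at least 1 CPM were tested.

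Of 89 cell division genes 8 were higher in Akibae and 4 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.11). The cell division list passed without Akibae replicate 3 (0.026), Nijisseiki replicate 2 (0.017), SuCui NO.1 replicate 2 (0.03) or CuiYu replicate 1 (0.049), and without the filter on low counts (0.019). Of 96 heat shock genes 10 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.62), and of 123 defence genes 4 and 4 (2 and 3 adjusted over the list alone, 0.96). Heat shock 70 kDa protein 14 (gene9658), a chaperone, fell by 1.03 ± 0.16 (SE, adjusted p = 0.0027), and stood at 74.8 ± 5.21 CPM in Akibae and 77.6 ± 8.33 in Nijisseiki against 245 ± 61.45 in SuCui NO.1. Histone H4 (gene30413), at 7.57 ± 7.16 CPM in Akibae, was higher by 4.03 ± 0.75 (adjusted p = 0.0068, and by 3.03 at 0.074 without Akibae replicate 1). Histone H3.2 (gene12242) had 2 reads in Akibae, and its ratio to Akibae was 73.5 in CuiYu (95% counting interval 20.01 to 612), 19.6 in Nijisseiki (5.08 to 167.5, and 12.3 without Nijisseiki replicate 3) and 3.95 in SuCui NO.1 (0.788 to 38.2), an interval that includes no difference. Its adjusted p of 0.048 became 0.065 to 0.18 without any 1 library except Nijisseiki replicate 1 and SuCui NO.1 replicate 1, and 0.054 without the filter on low counts. A 17.3 kDa class II heat shock protein (gene1367), at 362 ± 348 CPM in Akibae and 156 ± 151 in Nijisseiki, was higher by 4.28 ± 1.04 (adjusted p = 0.026, by 3.37 without Akibae replicate 1 and by 5.23 without SuCui NO.1 replicate 3), a call that ended at 0.052 to 0.15 without Akibae replicate 1 or 2, Nijisseiki replicate 3 or CuiYu replicate 2 or 3. A basic pathogenesis-related protein 1 (gene34362) was higher by 2.83 ± 0.69 (adjusted p = 0.027, and by 2.07 without Akibae replicate 2), which ended at 0.052 to 0.21 without Akibae replicate 2 or 3 or any 1 CuiYu library. The major allergen Pru ar 1 (gene37651) fell by 4.72 ± 1.30 (adjusted p = 0.044, and by 4.13 without Akibae replicate 3), with its Akibae reads all in replicate 2. This call ended at 0.051 to 0.15 without Akibae replicate 1 or 3, Nijisseiki replicate 2, SuCui NO.1 replicate 2 or 3 or any 1 CuiYu library. Xyloglucan endotransglucosylase/hydrolase 9 (gene33560), a wall-remodelling enzyme with 3 reads in Akibae and 23.8 ± 18.6 CPM in Nijisseiki (adjusted p = 0.022), had 6 reads in SuCui NO.1, a ratio to Akibae of 1.97 (95% counting interval 0.422 to 12.2, and 3 and 0 without SuCui NO.1 replicates 2 and 3), and a ratio of 79.15 in CuiYu (26.8 to 386). It lost its call without any 1 Akibae library (0.069 to 0.099) or without SuCui NO.1 replicate 3 (1.0).

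Of 9 vascular genes 1 was higher in Akibae and 0 lower (also 1 and 0 adjusted over the list alone, camera adjusted p = 0.44), and of 62 genes of sugar-storing flesh 4 and 4 (6 and 6 adjusted over the list alone, 0.96). The phloem gene SIEVE ELEMENT OCCLUSION B (gene37837) stood at 15.7 ± 18.6 CPM in Akibae and 0.547 ± 0.597 in Nijisseiki, with a mean of 3.34 in SuCui NO.1 and 2 reads in CuiYu. It was higher by 5.05 on the log2 scale (adjusted p = 0.0048), by 3.37 without Akibae replicate 3 (adjusted p = 0.044) and by 5.93 without CuiYu replicate 3. Polyol transporter 5 (gene36166) fell by 4.97 ± 0.80 (SE, adjusted p = 0.003). A sucrose synthase (gene35276) was higher by 2.08 ± 0.55 (adjusted p = 0.036), which ended at 0.053 to 0.16 without any 1 Akibae library, Nijisseiki replicate 2 or any 1 CuiYu library. Of 295 cytosolic ribosome genes 14 were higher and 4 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.18), and the list passed without SuCui NO.1 replicate 3 (0.00054) or Akibae replicate 1 (0.011). The 60S protein L3 (gene29744) was at 1.28 ± 0.583 CPM in Akibae and 1.73 ± 0.293 in CuiYu against 421 ± 56.5 in Nijisseiki and 244 ± 97.9 in SuCui NO.1 (adjusted p = 1.8e-05). The ribosomal gene 60S L12 (gene3532) stood at 5.88 ± 0.443 CPM in Akibae and had 0 reads in SuCui NO.1 (adjusted p = 0.00022), with means of 3.83 in Nijisseiki and 1.03 in CuiYu.

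Among named genes that differed between Akibae and each other variety, cytochrome P450 71A4 (gene27907, chromosome 17, 5925202 to 5926938), of a large family of plant oxidases, was the most abundant in Akibae. It stood at 388 ± 111 CPM in Akibae, 0.808 ± 0.796 in Nijisseiki and 2.46 ± 1.81 in SuCui NO.1, and had 3 reads in CuiYu (n = 3 each, adjusted p = 7e-06). A nucleobase-ascorbate transporter 3 (gene10378) stood at 12.03 ± 8.47 CPM in Akibae and had 0 reads in the other 9 libraries (adjusted p = 0.0021 against the mean of the others). This was at least 158-fold less in SuCui NO.1 (94.98-fold without Akibae replicate 3). A putative F-box protein (gene36338) and an LRR receptor-like kinase (gene28508) stood at 6.33 ± 1.96 and 5.46 ± 3.38 CPM in Akibae, the first with 0 reads elsewhere and the second with 1 read, in Nijisseiki (adjusted p = 0.0011 and 0.00079). Glutamate dehydrogenase (gene27291), which links ammonium and amino acids, had 0 reads in Akibae (adjusted p = 0.0069 against the mean of the others). It had at least 478-fold more in CuiYu, at 36.9 ± 4.03 CPM. It stood at 14.5 ± 12.8 CPM in Nijisseiki, with 0.26 CPM in the library labelled Nijisseiki replicate 1. A chloroplast ribosomal protein L31 (gene2983) and a retrovirus-related Pol polyprotein (chromosome 4, 16402518 to 16405451) also had 0 reads in Akibae and stood at 14.0 ± 6.31 and 15.7 ± 2.66 CPM in CuiYu (adjusted p = 0.013 and 4.1e-05). Up to 15 other genes in the table shared the Swiss-Prot name of one of these 8 genes, so the levels of single copies are uncertain where reads were split between near-identical genes, and the counting rule is not given in the sources used here.

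In total 2596 genes differed between Akibae and the mean of the other 3 varieties (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 1472 higher with a median log2 fold change of 1.93 and 1124 lower with a median of -2.07. A total of 65 genes were higher in Akibae than in each of the other 3 varieties and 215 were lower than in each. Independent lists of these sizes would share 1.35 and 2.89 genes, and 20 simulations of unchanged groups, with at most 1 call over the 3 tests, gave 0 in each. With so few calls the simulations could hardly give an overlap, and they say little about chance overlap among lists of the real sizes. The 3 tests share the Akibae libraries, so part of the excess may come from them. The count of 2596 became 1233 and 1272 without Akibae replicates 1 and 2 and 4198 with DESeq2, and the 215 became 107 and 108 without those libraries and 399 with DESeq2. The 65 became 23 without either of Akibae replicates 1 and 2, 35 and 34 without Nijisseiki replicates 2 and 3, 41, 41 and 43 without CuiYu replicates 1, 2 and 3, and 146 with DESeq2. This count also fell by over 1.5 times with the replicate number as a block, as given below. Without the library labelled Nijisseiki replicate 1 the 3 counts were 3204, 78 and 256.

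**Figure D4:**
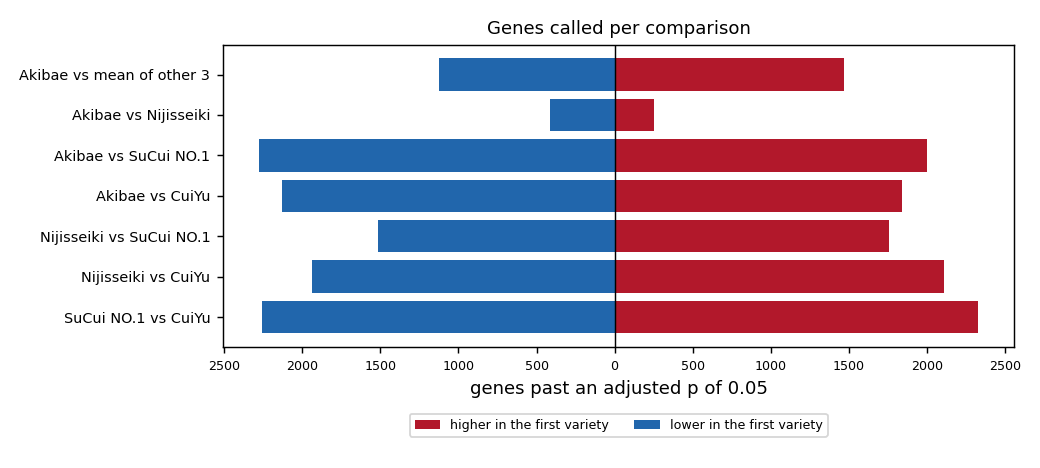
Genes past an adjusted p of 0.05 per comparison (edgeR, 26307 genes tested), with genes higher in the first variety drawn to the right and genes lower in it to the left on a linear axis of gene counts. Akibae against Nijisseiki has the fewest, with 253 higher and 412 lower.

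Akibae against Nijisseiki compared 2 varieties harvested at 120 and 135 days. Wax genes were again lower in Akibae, with 9 of 28 members lower and 0 higher (13 and 0 adjusted over the list alone), a median log2 fold change of -1.71 (-1.62 with members at 0 reads set to the floor) and a camera adjusted p of 1.1e-10. Of 23 cutin genes 3 were lower and 0 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.00034). These calls were lost at an adjusted p = 0.29 for wax and 0.75 for cutin with an estimated correlation. The wax gene 3-ketoacyl-CoA synthase 6 (gene8119, chromosome 13, 1079692 to 1081349) had 3 reads in Akibae against 20.05 ± 26.6 CPM in Nijisseiki, a ratio of 234 (95% counting interval 79.6 to 1136, adjusted p = 0.0098) that was 60.8 without the library labelled Nijisseiki replicate 1. Its call ended without Akibae replicate 1 (adjusted p = 0.06) or 2 (0.058) and in a fit of the 6 libraries alone (0.11). Photosynthesis genes were lower as a list (camera adjusted p = 0.00096), with 1 of 73 lower and 0 higher (also 1 and 0 adjusted over the list alone), and cell wall loosening genes were higher (adjusted p = 0.016), with 3 of 122 higher and 1 lower (4 and 2 adjusted over the list alone). Both had an adjusted p = 0.99 with an estimated correlation. The photosynthesis call ended without Nijisseiki replicate 2 (0.99), and that of wall loosening without Akibae replicate 2 (0.072) or the library labelled Nijisseiki replicate 1 (0.14). The chlorophyll a-b binding protein 6 gene (gene25850) fell by 2.42 ± 0.35 (SE, adjusted p = 0.0047, and 0.071 with the 6 libraries alone), from 23.7 ± 12.2 CPM in Nijisseiki to 4.42 ± 0.323 in Akibae. Of the lists that did not pass with all libraries, suberin (0.031), lignin polymerisation (0.015) and cell division (0.011) passed without Nijisseiki replicate 2. Lignin polymerisation also passed with the 6 libraries alone (0.013), and cell division without Akibae replicate 3 (0.029), without Nijisseiki replicate 3 (0.048) or without the filter on low counts (0.042). Flavonoid genes (0.0013) and MYB factors (0.038) passed without the library labelled Nijisseiki replicate 1. Endoglucanase 1 (gene11341) was higher by 4.53 ± 0.82 (adjusted p = 0.016, by 3.68 at 0.067 without Akibae replicate 2, and 0.10 with the 6 libraries alone).

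Among the named genes with the largest differences between these varieties, the translation factor SUI1 homolog 2 (gene9597) stood at 52.1 ± 10.4 CPM in Akibae, at least 688-fold over the 0 reads of Nijisseiki (adjusted p = 4.7e-05). The nucleobase-ascorbate transporter gene10378 was at least 159-fold higher in Akibae (95.64-fold without Akibae replicate 3, adjusted p = 0.026). Its call ended without Akibae replicate 1 (0.058) or 2 (0.091) or Nijisseiki replicate 2 (0.053) or 3 (0.055), with DESeq2 (0.20), with the replicate number as a block (0.065) and with the 6 libraries alone (0.053). Beta-glucosidase 11 (gene6607) and ZINC INDUCED FACILITATOR-LIKE 1 (gene7227) had 0 reads in Akibae and were at least 320-fold and 243-fold higher in Nijisseiki (adjusted p = 0.0026 and 0.0021). In total 665 genes differed, 253 higher and 412 lower in Akibae, and in 13.2% of them 1 of the varieties had 0 reads. The count became 294 and 292 without Akibae replicates 1 and 2, 433 and 410 without Nijisseiki replicates 2 and 3, 442 without CuiYu replicate 2, 213 with the 6 libraries alone and 1636 with DESeq2. Without the library labelled Nijisseiki replicate 1 it was 929.

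Akibae against SuCui NO.1 compared varieties harvested at 120 and 105 days. Of 28 wax genes 17 were lower in Akibae and 0 higher (18 and 2 adjusted over the list alone), with a median log2 fold change of -1.78. Of 23 cutin genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone, median -1.19), and of 73 photosynthesis genes 17 were lower and 2 higher (25 and 3 adjusted over the list alone, median -1.49). The camera adjusted p was 5.4e-07, 0.0011 and 3.3e-06, and these calls were lost at an adjusted p = 0.40, 0.87 and 0.99 with an estimated correlation. The ratio of SuCui NO.1 to the 1 read of cytochrome P450 86A22 (gene23333) in Akibae was 1864 (95% counting interval 334.1 to 73650, adjusted p = 5.2e-05). The wax gene gene8119 stood at 30.2 ± 6.43 CPM in SuCui NO.1, 388 times its level in Akibae (counting interval 132.3 to 1882, adjusted p = 0.0017). Suberin genes did not pass (camera adjusted p = 0.23), but passed as higher in Akibae without SuCui NO.1 replicate 2 (adjusted p = 0.0053), the library in which they stood at a median of 15.9 CPM. Without that library lignin polymerisation (0.042) and cell wall loosening (0.03) also passed, as did wall loosening (0.044) and ribosome genes (2.2e-05) without SuCui NO.1 replicate 3 and flavonoid genes (0.043) without SuCui NO.1 replicate 1. A cyclic nucleotide-gated channel 10 (gene40680) and an RPP8-like resistance protein (gene38829) stood at 117 ± 79.4 and 43.6 ± 2.95 CPM in Akibae and had 0 reads in SuCui NO.1, at least 1530-fold and 572-fold less (adjusted p = 0.006 and 7.7e-07). Temperature-induced lipocalin-1 (gene16128) and a retrovirus-related Pol polyprotein (chromosome 1, 16428890 to 16444815) had 0 reads in Akibae and were at least 2419-fold and 796-fold higher in SuCui NO.1 (adjusted p = 0.0075 and 0.0002). The lipocalin stood at 187 ± 211 CPM in SuCui NO.1, and its bound was 873-fold without SuCui NO.1 replicate 3. In total 4282 genes differed, 2004 higher and 2278 lower in Akibae, and the count became 2440 and 2530 without Akibae replicates 1 and 2.

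Akibae against CuiYu compared varieties harvested at 120 and 105 days. Cutin genes were lower in Akibae, with 14 of 23 lower and 0 higher (14 and 2 adjusted over the list alone), a median log2 fold change of -2.48 and a camera adjusted p of 1.9e-11. Of 28 wax genes 16 were lower and 0 higher (20 and 3 adjusted over the list alone, median -2.70, camera adjusted p = 2.8e-10). Both calls were lost at an adjusted p = 0.29 with an estimated correlation. The ratio of CuiYu to Akibae was 10870 for cytochrome P450 86A22 (gene23333, 95% counting interval 1950 to 429300, adjusted p = 1.7e-05), and the lipid transfer protein gene21123 was at least 196-fold higher in CuiYu (adjusted p = 0.00023). Of 73 photosynthesis genes 8 were lower and 3 higher (10 and 4 adjusted over the list alone, camera adjusted p = 0.035), and of 295 ribosome genes 21 were higher and 11 lower (18 and 9 adjusted over the list alone, camera adjusted p = 0.013). Both had an adjusted p = 0.99 with an estimated correlation. The photosynthesis call ended without Akibae replicate 1 (0.079) or 2 (0.093) or CuiYu replicate 3 (0.065), and the ribosome call without Akibae replicate 2 (0.061) or 3 (0.064) or CuiYu replicate 2 (0.092). Lists that did not pass with all libraries but passed otherwise were suberin (0.049 without CuiYu replicate 1), phenylpropanoid entry (0.049 without CuiYu replicate 1, 0.034 with the 6 libraries alone and 0.045 without the filter on low counts), cell division (0.039 without Akibae replicate 3 and 0.021 without the filter) and lignin polymerisation (0.042 without SuCui NO.1 replicate 2 and 0.046 with a mean of at least 1 CPM). The ribosomal gene 60S L32-1 (gene27767) was higher by 5.99 ± 0.47 (SE, adjusted p = 2.6e-05), at 90.9 ± 17.9 CPM in Akibae against 1.43 ± 0.802 in CuiYu. A cysteine-rich receptor-like kinase 25 (gene33113) stood at 179 ± 52.6 CPM in Akibae, at least 2462-fold over the 0 reads of CuiYu (adjusted p = 5.8e-05), and the ratio for cytochrome P450 71A4 (gene27907) was 5358 (95% counting interval 1833 to 25990, adjusted p = 5.3e-05). Lipocalin-1 (gene16128) was at least 1573-fold higher in CuiYu (adjusted p = 0.0095). In total 3968 genes differed, 1840 higher and 2128 lower in Akibae. The count became 2393 and 2347 without Akibae replicates 1 and 2, 2357 and 2287 without CuiYu replicates 1 and 2, and 6360 with the 6 libraries alone.

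Nijisseiki against SuCui NO.1 compared varieties harvested at 135 and 105 days. Of the 20 lists, photosynthesis passed camera, with 8 of 73 members lower in Nijisseiki and 2 higher (also 8 and 2 adjusted over the list alone), a median log2 fold change of -0.42 and an adjusted p of 0.019. The call was lost at an adjusted p = 0.99 with an estimated correlation, and without the library labelled Nijisseiki replicate 1 (0.52), Nijisseiki replicate 3 (0.10), SuCui NO.1 replicate 2 (0.36) or with the 6 libraries alone (0.06). Ribosome genes passed without SuCui NO.1 replicate 3 (8.2e-05), suberin genes without SuCui NO.1 replicate 2 (0.034) and wax genes without the library labelled Nijisseiki replicate 1 (0.019). In a fit of the 6 libraries with the replicate number as a block, added after the pairing of the numbers was seen, photosynthesis kept its call. Phenylpropanoid entry genes passed in that fit (0.014). The chlorophyll binding protein CP24 10A (gene13067) fell by 2.97 ± 0.81 (SE, adjusted p = 0.035, by 3.87 without Nijisseiki replicate 2 and by 2.35 without SuCui NO.1 replicate 2), and this call ended at 0.053 to 0.11 without the library labelled Nijisseiki replicate 1, Nijisseiki replicate 3, SuCui NO.1 replicate 2 or 3, any 1 CuiYu library, or with the 6 libraries alone. Calmodulin-binding transcription activator 2 (gene22570), a calcium-responsive regulator, stood at 41.7 ± 4.92 CPM in Nijisseiki, at least 547-fold over the 0 reads of SuCui NO.1 (adjusted p = 1.3e-06). The channel gene40680 was at least 980-fold higher in Nijisseiki, at 74.7 ± 65.7 CPM (620-fold without Nijisseiki replicate 2, adjusted p = 0.0091, and 0.084 with the 6 libraries alone). A retrovirus-related Pol polyprotein (chromosome 1, 16428890 to 16444815) and rubisco activase 1 (gene39096), which keeps the carbon-fixing enzyme active, had 0 reads in Nijisseiki and were at least 812-fold and 629-fold higher in SuCui NO.1 (adjusted p = 0.0002 and 0.011, the latter 0.063 with the 6 libraries alone). Rubisco activase 1 stood at 47.6 ± 62.3 CPM in SuCui NO.1, and its bound was 155-fold without SuCui NO.1 replicate 1. In total 3270 genes differed, 1756 higher and 1514 lower in Nijisseiki. The count became 2100 and 2135 without Nijisseiki replicates 2 and 3, 1222 with the 6 libraries alone, 1307 with these and the replicate block, and 5138 with DESeq2, and it was 4638 without the library labelled Nijisseiki replicate 1.

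Nijisseiki against CuiYu compared varieties harvested at 135 and 105 days. Cuticle genes were lower in Nijisseiki, with 13 of 23 cutin genes lower and 0 higher (13 and 3 adjusted over the list alone, median log2 fold change -1.82) and 6 of 28 wax genes lower and 1 higher (10 and 1 adjusted over the list alone, median -0.94). The camera adjusted p was 1.4e-06 for cutin and 0.0096 for wax, and the calls were lost at an adjusted p = 0.40 and 0.99 with an estimated correlation. BAHD acyltransferase DCR (gene32423), which is needed to build cutin, fell by 5.33 ± 0.56 on the log2 scale (SE, adjusted p = 0.00017, and by 6.0 without the library labelled Nijisseiki replicate 1), from 98.5 ± 9.32 CPM in CuiYu to 2.47 ± 1.64 in Nijisseiki. ECERIFERUM 1 (gene30156) fell by 3.82 ± 0.68 (adjusted p = 0.007, and by 4.48 without the same library). Of 13 phenylpropanoid entry genes 5 were higher in Nijisseiki and 0 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.016), and of 295 ribosome genes 27 were higher and 11 lower (26 and 11 adjusted over the list alone, camera adjusted p = 0.034). These calls were lost at an adjusted p = 0.75 and 0.99 with an estimated correlation. The ribosome call also ended without the library labelled Nijisseiki replicate 1 (0.065), Nijisseiki replicate 2 (0.054) or CuiYu replicate 2 (0.17). Photosynthesis passed without Nijisseiki replicate 2 (0.013) and flavonoid genes without the library labelled Nijisseiki replicate 1 (0.024). 4-coumarate--CoA ligase 2 (gene12072) was higher by 2.55 ± 0.76 (adjusted p = 0.044), and this call ended at 0.051 to 0.15 without Akibae replicate 1 or any 1 Nijisseiki or CuiYu library. The receptor-like kinase gene33113 and beta-glucosidase 11 (gene6607) had 0 reads in CuiYu and were at least 2212-fold and 340-fold higher in Nijisseiki (adjusted p = 6e-05 and 0.00071). SUI1 homolog 2 (gene9597) and an exosome subunit RRP42 (chromosome 9, 15209559 to 15210251) had 0 reads in Nijisseiki and were at least 2305-fold and 678-fold higher in CuiYu (adjusted p = 7.8e-06 and 0.00076). In total 4050 genes differed, 2112 higher and 1938 lower in Nijisseiki. The count became 2214, 2054 and 2636 without CuiYu replicates 1, 2 and 3 and 6229 with DESeq2, and it was 4075 without the library labelled Nijisseiki replicate 1.

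SuCui NO.1 against CuiYu compared the 2 varieties harvested at the same 105 days. Of 23 cutin genes 10 were lower in SuCui NO.1 and 2 higher (15 and 3 adjusted over the list alone), with a median log2 fold change of -1.42 and a camera adjusted p of 0.0002. Of 37 flavonoid genes 3 were higher and 0 lower (also 3 and 0 adjusted over the list alone, median 1.10, camera adjusted p = 0.016). These calls were lost at an adjusted p = 0.67 and 0.99 with an estimated correlation. The flavonoid call also ended without Akibae replicate 2 (0.058), SuCui NO.1 replicate 2 (0.089) or 3 (0.12) or CuiYu replicate 2 (0.088), and without the filter on low counts (0.096). Of 73 photosynthesis genes 6 were higher in SuCui NO.1 and 1 lower (5 and 0 adjusted over the list alone, median 0.67), and the list did not pass with all libraries (camera adjusted p = 0.058). It passed, at 0.0013 to 0.048, without SuCui NO.1 replicate 1 or 3, CuiYu replicate 3, Akibae replicate 3 or any 1 Nijisseiki library, with the 6 libraries alone (0.0051) and without the filter (0.041). Wax genes passed with the 6 libraries alone (0.0016, against 0.18 with all), and ribosome genes without SuCui NO.1 replicate 1 (6.7e-07, against 0.20). Long chain acyl-CoA synthetase 2 (gene23598), which activates fatty acids for cutin, fell by 2.96 ± 0.71 (SE, adjusted p = 0.017). Its call ended without SuCui NO.1 replicate 3 (0.057) or CuiYu replicate 1 (0.054) or 3 (0.052). Anthocyanidin reductase (gene40480), an enzyme of tannin synthesis, was higher by 3.45 ± 0.71 (adjusted p = 0.0081, and by 4.92 without CuiYu replicate 1), at 1.40 ± 0.125 CPM against 0.117 ± 0.144 in CuiYu. The receptor-like kinase gene33113 and a retrovirus-related Pol polyprotein (chromosome 1, 16428890 to 16444815) had 0 reads in CuiYu and were at least 2188-fold and 845-fold higher in SuCui NO.1 (adjusted p = 5.8e-05 and 0.00021), the first 1357-fold without SuCui NO.1 replicate 3. The transcription activator gene22570 had 0 reads in SuCui NO.1 and was at least 933-fold higher in CuiYu (adjusted p = 1.6e-06). In total 4587 genes differed, 2330 higher and 2257 lower in SuCui NO.1, and the count became 2509, 2307 and 2900 without CuiYu replicates 1, 2 and 3.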

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

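The alternatives were chosen before the data were examined, except the blocked fit of 6 libraries, which was chosen after the pairing of Nijisseiki and SuCui NO.1 was seen, and the planned settings for a table without raw counts, another pseudocount and no filter on low values, were not run because raw counts were there. No list or named gene result that passed both with the main settings and under an alternative turned its direction. With DESeq2's median-ratio factors, with upper-quartile factors, without a filter, with a mean of at least 1 CPM and with an added minimum log2 fold change of 1, no count of genes moved by over 1.5 times. With the DESeq2 Wald test the counts were 4198 for Akibae against the mean of the others, 1636 for Akibae against Nijisseiki, 5138 for Nijisseiki against SuCui NO.1, 6229 for Nijisseiki against CuiYu, and 146 and 399 for genes higher and lower in Akibae than in each other variety (the cause was not tested). With only the 6 libraries of the 2 varieties, Akibae against Nijisseiki gave 213 genes, Nijisseiki against SuCui NO.1 1222 and Akibae against CuiYu 6360, a fit in which the spread comes from fewer libraries. With an estimated correlation 0 of 21 list calls were left, at an adjusted p of 0.29 for wax, 0.30 for cutin and 0.99 for photosynthesis in Akibae against the mean of the others.

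Leaving out 1 library at a time, which leaves fewer libraries, gave 1233 to 3204 genes for Akibae against the mean of the others, 292 to 929 for Akibae against Nijisseiki, 2440 to 5462 for Akibae against SuCui NO.1, 2287 to 5016 for Akibae against CuiYu, 2100 to 4638 for Nijisseiki against SuCui NO.1, 2054 to 4633 for Nijisseiki against CuiYu and 2307 to 5896 for SuCui NO.1 against CuiYu. It gave 23 to 82 genes higher and 107 to 256 genes lower in Akibae than in each other variety, and 17 to 27 list calls. For Akibae against the mean of the others, the adjusted p ranged from 7.9e-17 to 2e-10 for wax, 1.9e-12 to 1.3e-06 for cutin and 7.5e-08 to 0.00015 for photosynthesis. The lowest counts came without Akibae replicate 1 or 2, Nijisseiki replicate 2 or CuiYu replicate 2, depending on the comparison, and without the library labelled Nijisseiki replicate 1 the counts of the 7 comparisons were 3204, 929, 5462, 5016, 4638, 4075 and 5896. Of the 91 results for a named gene, 71 passed the threshold without each library in turn and 20 lost their call without at least 1. Of the named gene results, 1 lost its call with DESeq2, 2 without a filter, 1 with a mean of at least 1 CPM and 7 of 53 with the 6 libraries alone, and none of the 91 with either scaling.

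The replicate numbers of the labels did not pair the libraries as a whole. Over 18 pairs of libraries with the same number, the correlation of their deviations from the variety means ran from -0.22 to 0.37 with a median of 0.01, 5 pairs were over 0.1, and 6 of the 12 libraries correlated best with their own number. In 1 of the 6 pairs of varieties, Nijisseiki and SuCui NO.1, all 3 pairs were over 0.1 (0.2 to 0.37, other pairs -0.32 to 0.1). Deviations within a variety cancel over its libraries, so these 3 correlations are not independent of each other. A fit of these 6 libraries with the replicate block gave 1307 genes in place of 1222 without it and 3270 with all 12 libraries. That fit kept the call of each of 7 named genes, and 1 of 20 list tests, phenylpropanoid entry, passed that had not. With the replicate block over all 12 libraries, 38 genes were higher in Akibae than in each other variety in place of 65, and the other 9 counts stayed within 1.5 times. With the block 6 of 91 named gene calls were lost. For Akibae against the mean of the others these were gene12127 (adjusted p = 0.071), gene12242 (0.086), gene1367 (0.069) and gene37651 (0.084). The others were gene10378 for Akibae against Nijisseiki (0.065) and gene12072 for Nijisseiki against CuiYu (0.053). With the block 5 of 140 list tests passed that had not, for Akibae against the mean of the others lignin polymerisation (0.026), cell division (0.045) and cell wall loosening (0.048), for Akibae against SuCui NO.1 cell wall loosening (0.023) and for SuCui NO.1 against CuiYu photosynthesis (0.047).

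Depth limits what low genes can show. A variety with 0 reads over its 3 libraries can still hold up to 0.0728 to 0.0772 CPM. In the simulated data, drawn from genes of any level, edgeR recovered 10 of 100 genes changed by a log2 of 1 in Akibae against the mean of the others. Depth was not varied there, so what limited this recovery was not tested.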

Other observations

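The tests of the regroupings and splits were planned before their results were seen, and the tests on single libraries, on harvest day, on flesh and on Akibae RNA were chosen only after the pattern or the genes had been seen. For the tests on Akibae RNA and on harvest day, the rules were changed after values had been seen.

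Between 7.15% of the calls, for SuCui NO.1 against CuiYu, and 13.2%, for Akibae against Nijisseiki, were on genes with 0 reads in 1 of the 2 varieties. In Akibae against SuCui NO.1, 202 called genes had 0 reads in SuCui NO.1 and 236 had 0 reads in Akibae. Against CuiYu the numbers were 162 and 248, for Nijisseiki against SuCui NO.1 202 and 134, and for Nijisseiki against CuiYu 160 and 149. Whether such a gene was silent, absent or too different in sequence to be counted was not tested.

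For Akibae against the mean of the others, only the real grouping, 1 of 60 regroupings, reached 2596 genes (highest other 778). The 65 genes higher and the 215 genes lower in Akibae than in each other variety were also reached by 1 of 60 regroupings in each case (highest others 5 and 2). No other regrouping kept all libraries of a variety in the place of Akibae. Groups that mix varieties hold the differences between them, which widens the spread and can lower the calls. The regroupings therefore show that the libraries differ by variety. They cannot show how many calls chance would give for Akibae alone. By the same permutation of the libraries, 1 of 60 reached the camera p of the wax list (p = 1.2e-13, lowest other 1.6e-07) and 1 of 60 that of the cutin list (p = 3.2e-10, lowest other 2.1e-07). Small camera p were not rare in other regroupings, such as 1.7e-06 and 7.1e-06 for wax and 5.1e-07 and 2.2e-06 for cutin. A small p with the preset correlation therefore says little alone. For photosynthesis, 25 of 60 regroupings gave a camera p as small as 5.5e-07, and the lowest other was 7.3e-45. For the 6 pairs of varieties, 10 splits are too few for a share under 0.05. The real split and the highest of the other 9 gave 665 and 1 genes for Akibae against Nijisseiki, 4282 and 2 for Akibae against SuCui NO.1, 3968 and 1 for Akibae against CuiYu, 3270 and 213 for Nijisseiki against SuCui NO.1, 4050 and 0 for Nijisseiki against CuiYu and 4587 and 1 for SuCui NO.1 against CuiYu. The split with 213 genes put the library labelled Nijisseiki replicate 1 together with SuCui NO.1 replicates 1 and 3.

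The library labelled Nijisseiki replicate 1 stood apart from replicates 2 and 3. Of 107 genes that were on (at least 10 CPM), or off (at most 0.5 CPM), throughout each of the other 3 varieties, 14 and 12 differed in state between it and replicates 2 and 3. Between replicates 2 and 3, 0 differed. In the same test of the other varieties 0 of 73 genes differed within Akibae, 0 of 63 within SuCui NO.1 and 0 of 74 within CuiYu. Another ripening state of the same genotype was predicted to give no more differences than those pairs, and the 14 were more. That test cannot decide, since each of those pairs came from a single harvest day. They do not show how many genes a change of ripening state would switch. Fruit of Nijisseiki mixed with another genotype would keep genes on, yet 8 of these genes were on in replicates 2 and 3 and off in replicate 1, such as gene34486 (48.63 and 53.08 against 0.17 CPM) and gene24859 (24.28 and 18.42 against 0.09 CPM). The values needed by a library of another genotype are there, with at least 12 differences in each of its pairs, and this may be a fruit or tree of another pear. Over all genes, however, it differed in state from Akibae in 138 to 165 genes, from SuCui NO.1 in 214 to 235 and from CuiYu in 259 to 280, so that none of these varieties is a match. Nijisseiki replicates 2 and 3 differed from Akibae in 75 to 101 genes, fewer than the 118 to 137 between them and replicate 1. The values do not tell which of the libraries labelled Nijisseiki are of that variety. A sport or graft chimera within Nijisseiki was not tested. Variants called from the reads would test it and another genotype.

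For the wax and cutin genes that were lower in Akibae, Akibae lies between the other harvest days. A steady trend with days, with no difference between varieties beside it, would put Nijisseiki at or below Akibae. Of 20 members lower in Akibae than in SuCui NO.1 and in CuiYu, in 2 fits of 6 libraries that held no Nijisseiki library, 0 were at or below the Akibae level in Nijisseiki and 12 were called lower in Akibae than in Nijisseiki, and of all 51 tested members 5 were at or below it. Without the library labelled Nijisseiki replicate 1, these numbers were 1 of 20 and 10 of 51. Of the 20, 14 were lower in each Akibae library than in Nijisseiki replicates 2 and 3. This argues against a steady trend alone for most of these genes but not for each. The 20 members were picked for low values in the same Akibae libraries, which makes Nijisseiki values above them more likely. Each variety was taken on 1 day, so a steady trend beside a difference between varieties stays open. A larger share of flesh in the Akibae peel stays open, since the flesh list had a median log2 fold change of -0.02 with quartiles of -0.65 and 0.61 over its 62 members, and the vascular list one of 0.20 with quartiles of -0.04 and 1.88 over 9 members. A hypothesis that remains is that the brown skin of Akibae makes less cuticle. Lower levels of cutin genes were not particular to Akibae, however. Against CuiYu, 13 of 23 cutin genes were also lower in Nijisseiki (0 higher) and 10 in SuCui NO.1 (2 higher). Against Nijisseiki, 3 of 23 were lower in Akibae and 0 higher. Variety and day cannot be told apart for any effect of day that stands beside a difference between varieties. Skin of the 4 varieties taken on the same days would test the hypothesis.

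The suberin genes differed between libraries of the same variety, with a median of 15.9 CPM in SuCui NO.1 replicate 2 against 2.68 and 2.15 in replicates 1 and 3. If Akibae RNA had entered that library, it would need a share of 79.9% to reach its suberin levels, but 67 genes on in Akibae and off in SuCui NO.1 replicates 1 and 3 stood at a median of 0% of the Akibae level (upper quartile 0.621%), which argues against it. A fruit of another genotype is argued against as well, since 0 of the genes on or off throughout each other variety differed between SuCui NO.1 replicate 2 and either other replicate. In Nijisseiki replicate 2, 16 of 23 suberin members lay above each Akibae library and each other Nijisseiki library. RNA at the levels of those libraries could not, when mixed, give these 16. The library was looked at because its suberin level was high, and the fruits in a mixture may have differed from those sampled. Only 3 genes were on in Akibae and off in Nijisseiki replicates 1 and 3, under the 5 needed for the test used in SuCui NO.1. Whether Akibae RNA entered Nijisseiki replicate 2 was therefore not decided. Both libraries carry the replicate number 2. Nijisseiki and SuCui NO.1 were the varieties whose libraries of the same number deviated together, at a correlation of 0.2 to 0.37, and 0.36 for number 2. The deviations within a variety cancel over its libraries, so these correlations are not independent of each other. Those of Nijisseiki replicates 2 and 3 ran against those of the library labelled Nijisseiki replicate 1 (correlation -0.78 and -0.71), which stood apart. Whether the shared number has a part in the suberin levels was not tested. Patches of russet on single fruits may be a candidate explanation, which the labels do not allow to be tested and which separate sampling of russet and smooth patches would test.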
